A study of Mus musculus with 12 samples.

How the data were processed

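RNA was measured in 12 mouse kidneys, 3 in each of 4 groups, by single-end sequencing of strand-specific libraries with reads of 100 bp on an Illumina HiSeq instrument, per the labels' protocols. All libraries ran in lane 8 of one flow cell, and the labels name no other batch. Per the submitters' processing notes, reads were aligned to the mouse genome build GRCm38.p4 with TopHat2 2.1.0 and Bowtie2 2.2.5 and counted with featureCounts. The featureCounts version, its strand setting, its treatment of reads shared between genes and the annotation release are not given in the sources used here.

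The deposited table holds raw read counts, as whole numbers, for 13124 genes named by Entrez identifier in 12 libraries. Totals ran from 13200930 to 16324215 counts per library. Levels are in CPM, counts scaled to a common library size. The third-highest CPM of a gene was 2.01 or more for every gene in the table, so a minimum of about 2 CPM in 3 libraries had been applied before these counts were deposited; this filter is read from the values and no label states it. Genes below it were not analysed here. A symbol was found for 13074 genes through the RefSeq gene table of GRCm38.p6, used for names alone; the 50 genes without one held 0.0811% of all counts. Coordinates are GRCm38 positions from the GENCODE vM21 annotation, counted from 1.

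Groups were taken from the labels. Kidneys were numbered 1 to 12 across the study, no number occurs in 2 groups, and no pairing was used. Pairs of kidneys within a group differed by a chi-square per degree of freedom of 5.46 to 65.3, so none agreed within sampling noise and each counted as 1 replicate.

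Differences were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling factors and a robust quasi-likelihood fit over all 12 libraries, which shared 1 estimate of the spread with 8 residual degrees of freedom. The common biological coefficient of variation was 16.4%. The filter of edgeR (filterByExpr) removed no gene. A gene was called at a Benjamini-Hochberg (BH) adjusted p below 0.05 over the 13124 genes of that comparison, and "rose" and "fell" are used of called genes alone. CPM values are scaled by the TMM factors and given as mean ± SD over the 3 kidneys of a group. Log2 changes are edgeR's, with a standard error (SE) computed from the change and its test statistic.

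The 28 gene lists of cell types and pathways were tested with fry of limma 3.58.1 on log2 CPM with a prior count of 2, BH-adjusted over the 25 lists with at least 3 measured genes. Fry asks whether the genes of a list moved one way on balance and does not compare them with other genes. Each list was also tested with camera, which does make that comparison, with a preset correlation of 0.01 and with a correlation estimated from the data. The p called "with an estimated correlation" is camera's adjusted p from the second. Counts of called members are given over all genes tested and, where this differs, adjusted over the list alone. Fry's values depended slightly on the order of the library columns, so 100 random orders were also run. The level of a list in a kidney is the mean log2 CPM of its members minus the mean of the sham kidneys.

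The fit, the comparisons, the lists, the rule for naming genes and most alternatives were chosen before the data were examined. By that rule the named genes were Csf3r and C5ar1, with Csf3 and Hc, which had no entry in the table. Added to them in each comparison with the isotype group were the 5 called genes with the largest rise and the 5 with the largest fall. These needed 3 kidneys of one group above all 3 of the other and a mean log2 CPM of at least 1. The rule also took the list members with the smallest p: 2 from each of the neutrophil, tubule injury, proximal tubule and complement lists, and 1 from every other called list. The text prints some of these in full and summarises the rest. One gene that the rule names is not reported here. Cxcr2 and Spink8 were named after their values were seen.

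The alternatives tried were RLE and upper-quartile factors, library totals alone, other filters on low counts, DESeq2 1.42.0, limma-voom with and without sample weights, only the 6 libraries of the compared groups, a fit without the robust option, a test against a change of 1.5-fold and each library left out in turn. Chosen after the data were seen were the fits without kidneys 9 and 11 together, the orders of the libraries in fry, the injury position and the simulation of calls shared between comparisons, which draws genes independently of each other. That position places a kidney on a scale from the sham mean (0%) to the isotype mean (100%) over genes that differ between these groups.

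The gene test and fry were tested on simulated data with the means, totals and spread of the real libraries, with 50 genes changed at each size. A change of 2-fold was called for 62% of the genes in isotype against sham, 72% in anti-G-CSFR against isotype, 86% in anti-C5 against isotype, 72% in anti-G-CSFR against anti-C5, 62% in anti-G-CSFR against sham and 66% in anti-C5 against sham. At 1.5-fold these shares were 26%, 30%, 32%, 34%, 24% and 28%, in the same order. Unchanged genes gave 4, 12, 6, 7, 7 and 6 false calls. Bounds for a gene with no counts in a group use 3 counts over that group and cover counting error only.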

Results

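RNA was profiled in whole kidneys of male C57BL/6 mice 24 h after sham surgery or after unilateral warm renal ischaemia-reperfusion injury (IRI), in which the blood supply of a kidney is stopped and then restored. The labels do not say whether the kidney taken after IRI was always the operated one. The kidneys were flushed with saline before RNA was extracted from all their cells. The 4 groups held 3 kidneys each, from separate mice: untreated sham kidneys (1 to 3), and IRI kidneys of mice given an isotype control antibody (4 to 6), an antibody against the granulocyte colony-stimulating factor receptor G-CSFR (7 to 9) or an antibody against complement protein C5 (10 to 12). Antibodies were given 24 h before IRI. Between 13200930 and 16324215 reads were counted per kidney over 13124 genes.

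The targets of the antibodies were looked up first. Csf3r (Entrez 12986, GRCm38 chromosome 4, 126024550 to 126044440), the protein-coding gene of G-CSFR, is expressed mainly by neutrophils and their precursors. It stood at 1.49 ± 0.380 CPM (SD, n = 3) in sham kidneys, 11.4 ± 3.96 in the isotype group, 0.714 ± 0.436 under anti-G-CSFR and 6.24 ± 8.63 under anti-C5, where kidney 11 alone held 16.2 CPM. C5ar1 (Entrez 12273, chromosome 7, 16246743 to 16259540), which encodes a receptor for the C5 fragment C5a, stood at 1.52 ± 0.580, 9.18 ± 1.41, 2.23 ± 1.21 and 3.85 ± 3.68 CPM in the same order. Both rose in the isotype group against sham, by 2.92 ± 0.849 (SE) and 2.59 ± 0.584 on the log2 scale (edgeR quasi-likelihood test, BH-adjusted p = 0.0101 and 0.00227). Both fell under anti-G-CSFR against isotype, with log2 changes of −3.97 ± 0.943 and −2.05 ± 0.564 (edgeR BH-adjusted p = 0.00318 and 0.00749). Under anti-C5 against isotype neither passed the test, at −0.86 ± 0.749 and −1.25 ± 0.536 (edgeR BH-adjusted p = 0.335 and 0.0613). Without kidney 11 both passed, at −3.17 and −2.40 (adjusted p = 0.000109 and 0.000435; range over all alternatives 0.000109 to 0.678 for Csf3r and 0.000145 to 0.192 for C5ar1). With all 12 libraries limma-voom also called both, at −1.853 and −1.637 (limma-voom BH-adjusted p = 0.0316 and 0.00825). DESeq2 called C5ar1 at −1.254 (DESeq2 BH-adjusted p = 0.0419), so these calls depended on the method as well as on kidney 11. Hc, the mouse gene of C5, and Csf3, that of G-CSF itself, had no entry in the table.

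The comparison of isotype-treated IRI kidneys with sham kidneys asked what the injury did to kidney gene expression. Sham mice were given no antibody, so the contrast joins the injury with the injection of the isotype antibody. Genes of damaged tubule cells rose steeply, while genes of working tubule segments fell. Havcr1 (Entrez 171283, GRCm38 chromosome 11, 46735080 to 46779578), which encodes kidney injury molecule KIM-1, went from 6.90 ± 6.39 CPM in sham kidneys (SD, n = 3) to 3931 ± 1508 (n = 3). Krt20 (Entrez 66809, chromosome 11, 99428403 to 99438150), a keratin of stressed epithelium, went from 1.05 ± 0.487 to 1066 ± 399 CPM, and Lcn2, which encodes the iron-carrier-binding protein NGAL, from 15.0 ± 1.44 to 2213 ± 1036 CPM. Their log2 changes were 9.15 ± 2.08 (SE), 9.98 ± 1.81 and 7.21 ± 1.51 (edgeR BH-adjusted p = 0.00277, 0.000706 and 0.0017). The muscle filamin Flnc and the membrane protease Adam8 also ranked among the 5 largest rises, at 8.18 ± 1.46 and 6.52 ± 1.16.

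All 23 measured genes of the tubule injury list rose, with a median log2 change of 3.82 (fry, BH-adjusted p = 0.00109), which stayed at 3.82 with Sprr2f, a gene without counts in sham kidneys, set at its bound. All 30 proximal tubule genes fell, with a median of −2.44 (adjusted p = 3.89e-05). Among these, Slc22a8 (Entrez 19879, chromosome 19, 8591254 to 8611835), an organic anion transporter, went from 500.1 ± 11.2 to 104 ± 6.34 CPM, and the water channel Aqp1 from 1222 ± 172 to 136 ± 8.07 CPM. Of 13 loop of Henle and distal tubule genes, 11 fell (median −1.98, adjusted p = 5.73e-05), and the one with the smallest p was Slc12a1, the salt cotransporter of the thick ascending limb, which went from 1569 ± 44.7 to 101 ± 4.29 CPM. Of 13 collecting duct genes, 8 fell and 1 rose (median −0.45, adjusted p = 0.000644), among them the vasopressin receptor gene Avpr2, with a log2 change of −2.13 ± 0.258. Camera gave adjusted p = 0.642 with an estimated correlation for each of these 4 lists. The largest falls left genes close to 0 in the isotype group. The glycosyltransferase gene A4gnt stood at 26.6 ± 2.74 CPM in sham kidneys and 0.101 ± 0.0721 in the isotype group, and Prok1, which encodes a secreted prokineticin, at 6.95 ± 1.07 and 0.0185 ± 0.0321. Nat8f6, of an acetyltransferase gene family, and Nccrp1 fell by 6.29 ± 0.555 and 5.96 ± 0.583 on the log2 scale (edgeR BH-adjusted p = 6.09e-06 and 9.87e-06). Reads shared with similar genes of that family may make the counts of Nat8f6 uncertain, which was not measured.

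Genes of neutrophils rose in the isotype group: 12 of 13 did, with a median log2 change of 3.16 (fry BH-adjusted p = 0.0109). They included S100a8, a subunit of calprotectin, from 2.05 ± 0.605 to 18.4 ± 9.73 CPM, and the receptor gene Clec4d, from 0.178 ± 0.0353 to 5.38 ± 1.46 CPM. The exception, G0s2, which encodes a lipase inhibitor also made in fat and liver, fell from 65.4 ± 11.2 to 15.2 ± 4.19 CPM. The other listed neutrophil genes had no entry in the table. A gene low in sham kidneys could pass the filter of about 2 CPM in 3 libraries through the isotype kidneys alone, as Retnlg did. The count of neutrophil genes that rose is therefore partly set by that filter. All 16 fibroblast and matrix genes rose (median 1.93, adjusted p = 0.00231), with the contractile protein gene Tagln going from 25.0 ± 2.2 to 269 ± 34.0 CPM. Cell death genes rose, 11 of 13 (median 1.22, adjusted p = 0.000644), among them Bax, which opens the mitochondrial membrane, at 1.22 ± 0.142. Of 7 endothelial activation genes 4 rose and 1 fell (median 1.34, adjusted p = 0.00225), among them Thbd, which encodes thrombomodulin, at 1.63 ± 0.174. Fatty acid oxidation genes fell, 19 of 21, while 1 rose (median −1.07, adjusted p = 0.000607), as did genes of the dendritic cell and antigen presentation list, 6 of 7, while 1 rose (median −1.37, adjusted p = 0.0116). This list, called dendritic cell genes below, was measured mostly through MHC class II genes, which are not particular to dendritic cells. Several of its dendritic cell markers had no entry in the table. Decr1, a mitochondrial enzyme for unsaturated fatty acids, and the MHC class II gene H2-Eb1 changed by −1.77 ± 0.164 and −1.36 ± 0.283. In the antioxidant list 6 of 11 genes rose and 2 fell, or 7 and 2 adjusted over the list alone (median 1.03, adjusted p = 0.00325); Gstm1, a glutathione transferase, was one that fell, by 1.48 ± 0.127. For each of these 7 lists the adjusted p with an estimated correlation was 0.642. In the lists named so far the other counts adjusted over the list alone were the same as those over all genes.

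The remaining 4 called lists each lost the call when single kidneys were left out. Monocyte and macrophage genes (7 of 16 rose and 1 fell, median 0.66, fry BH-adjusted p = 0.0207) lost it without kidney 1, 3, 4 or 6 (0.0891, 0.0566, 0.242 and 0.0502), though Cd68, the member with the smallest p, rose to 27.7 ± 2.70 CPM. Chemokine and cytokine genes (6 of 12 rose, median 2.23, adjusted p = 0.0329) lost it without any of kidneys 1 to 6 (0.0891, 0.0669, 0.0795, 0.162, 0.0629 and 0.0501). Coagulation genes (8 of 11 rose and 1 fell, median 2.31, adjusted p = 0.0269) lost it without kidney 1, 3, 4, 5, 6 or 10 (0.0668, 0.0804, 0.075, 0.063, 0.0513 and 0.105). Hypoxia and glycolysis genes (4 of 17 rose and 9 fell, median −0.38, adjusted p = 0.0109) lost it without kidney 1 or 4 (0.059 and 0.0515) and with library totals as the scaling (0.123). Over all alternatives these adjusted p ran from 0.000767 to 0.242, 0.000703 to 0.162, 7.22e-06 to 0.105 and 0.00194 to 0.123. With an estimated correlation the adjusted p was 0.648 for the first 2 lists and 0.642 for the other 2. The colony-stimulating factor gene Csf1 rose by 2.56 ± 0.454 and the glucose transporter gene Slc2a1 by 1.38 ± 0.126, whereas F5, which encodes coagulation factor V, fell by 2.04 ± 0.137.

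In total 8241 of 13124 genes were called (edgeR, BH-adjusted), 4207 higher and 4034 lower, of which 1389 and 1862 by more than 2-fold. In 9082 genes (69.2%) the 3 kidneys of one group all lay above the 3 of the other, which chance gives in 10%. Scaling by library totals alone moved the median log2 change of all genes from 0.03 to 0.227 and gave 5586 higher and 3095 lower calls, 64.35% higher in place of 51.05%, so directions are relative to the TMM scaling. Without kidneys 9 and 11 the counts were 4256 higher and 4142 lower. Genes of ribosomal proteins, 76 in number, stood 1.03, 0.424 and 0.521 above sham on the log2 scale in kidneys 4 to 6.

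**Figure D1:**
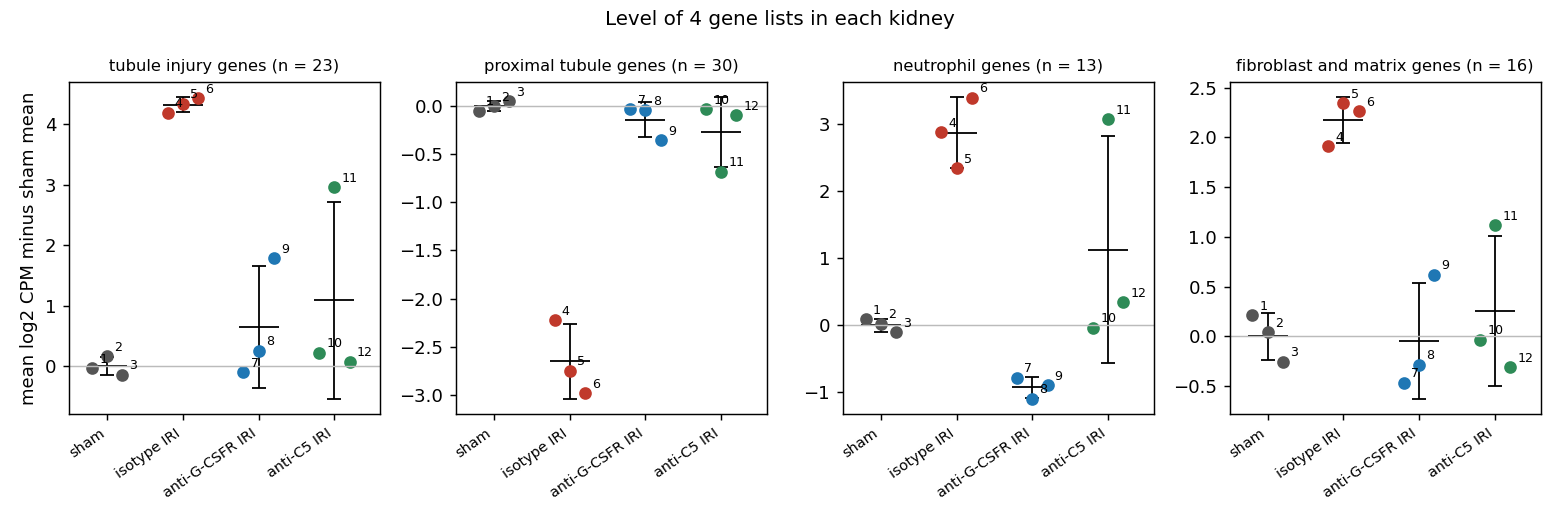
Level of 4 gene lists in each of the 12 kidneys, as the mean log2 CPM of the list minus the sham mean, by group, with points for kidneys and bars for mean ± SD (n = 3). In the tubule injury panel kidneys 4 to 6 lie between 4.18 and 4.43, while kidneys 9 and 11, at 1.78 and 2.96, stand apart from the other antibody-treated kidneys.

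Mice given anti-G-CSFR were compared with those given the isotype antibody to ask whether blocking the receptor altered the injured kidney. Under anti-G-CSFR, tubule injury genes were lower and tubule segment genes higher than in the isotype group, and neutrophil genes were lower too. All 23 tubule injury genes fell, with a median log2 change of −3.14 (fry BH-adjusted p = 0.00166), and all 30 proximal tubule genes rose, with a median of 2.44 (adjusted p = 6.25e-05). Of 13 neutrophil genes, 12 fell and G0s2 rose, with a median of −5.06, or −5.00 with Clec4e, a gene without counts under anti-G-CSFR, set at its bound (adjusted p = 0.00189). The filter on the table could keep genes high in the isotype kidneys alone, so it partly sets this neutrophil count too. With an estimated correlation the adjusted p was 0.539 for each of these 3 lists.

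Krt20 stood at 6.32 ± 6.92 CPM (SD, n = 3) under anti-G-CSFR, a log2 change of −7.41 ± 1.56 (SE) against isotype, Lcn2 at 59.9 ± 82.0, a change of −5.21 ± 1.37, and Flnc at 1.02 ± 0.626, a change of −7.44 ± 1.38 (edgeR BH-adjusted p = 0.0018, 0.00644 and 0.000828). Havcr1 fell by 4.86 ± 1.69 to 136 ± 182 CPM (edgeR BH-adjusted p = 0.0266), a call lost without kidney 4, 7 or 8 (0.0633, 0.0696 and 0.0822; range over all alternatives 3.95e-05 to 0.0822). The stress proteins Cryab, a small heat shock protein, and Anxa1, an annexin, had the smallest p of the tubule injury list, with changes of −1.90 ± 0.161 and −2.41 ± 0.241. Slc22a8 was at 454 ± 40.3 CPM and Aqp1 at 1123 ± 135, rises of 2.13 ± 0.145 and 3.05 ± 0.241. A4gnt was at 23.1 ± 5.52 CPM and Prok1 at 5.47 ± 0.546. Nat8f6 rose by 6.48 ± 0.556, Pvalb, a calcium-binding protein of the distal convoluted tubule, by 5.63 ± 0.607, and Sectm1b by 5.44 ± 0.405 (edgeR BH-adjusted p = 7e-06, 2.1e-05 and 4.1e-06). Loop and distal tubule genes rose, 11 of 13 (median 1.92, fry adjusted p = 0.000103), as did 8 of 13 collecting duct genes (median 0.49, adjusted p = 0.00112). Camera gave adjusted p = 0.539 with an estimated correlation for both. Slc12a1 was at 1152 ± 315 CPM, and Slc4a1, the anion exchanger of intercalated cells and red cells, rose by 3.48 ± 0.433.

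Among the neutrophil genes S100a8 fell by 5.56 ± 1.17 to 0.367 ± 0.313 CPM (edgeR BH-adjusted p = 0.00151). Retnlg, a resistin-like gene of granulocytes, stood at 5.89 ± 4.78 CPM in the isotype group and 0.169 ± 0.0483 under anti-G-CSFR, and Clec4d at 5.38 ± 1.46 and 0.0501 ± 0.0434 CPM. All 16 fibroblast and matrix genes fell (median −1.93, fry BH-adjusted p = 0.00175), with Tagln at 32.1 ± 5.64 CPM. Cell death genes fell, 11 of 13 (median −1.01, adjusted p = 0.00118), including the necroptosis effector Mlkl at −3.24 ± 0.452, and so did 5 of 7 endothelial activation genes (median −1.19, adjusted p = 0.00118), with Thbd at −1.76 ± 0.175. Fatty acid oxidation genes rose, 16 of 21, while 1 fell (median 0.93, adjusted p = 0.00124), with Decr1 at 1.59 ± 0.163. In the antioxidant list 6 of 11 fell and 2 rose, or 7 and 2 adjusted over the list alone (median −1.27, adjusted p = 0.00166), and Gstm1 was one of those that rose, by 1.33 ± 0.126. For each of these 5 lists the adjusted p with an estimated correlation was 0.539. The other counts in the lists named so far were the same adjusted over the list alone.

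For 6 further lists the call was lost without single kidneys. These were dendritic cell genes (6 of 7 rose and 1 fell, median 1.29, fry BH-adjusted p = 0.0152), lost without kidney 5 or 8 (0.0519 and 0.0542), and endothelial genes (6 of 12 fell, median −0.43, adjusted p = 0.0101), lost without kidney 5 (0.0519). Complement component genes (6 of 16 rose and 1 fell, median 0.42, adjusted p = 0.0254) lost it without kidney 5, 8 or 9 (0.0729, 0.078 and 0.0832) and coagulation genes (1 of 11 rose and 5 fell, median −1.02, adjusted p = 0.0222) without kidney 4, 5, 7, 8 or 10 (0.0558, 0.0595, 0.0758, 0.078 and 0.0773). Heat shock genes (2 of 10 rose and 5 fell, median −0.52, adjusted p = 0.0358) lost it without any of kidneys 1 and 4 to 9 (0.0651, 0.404, 0.0729, 0.0598, 0.0936, 0.0722 and 0.0791), and monocyte and macrophage genes (1 of 16 rose and 8 fell, 7 adjusted over the list alone, median −0.69, adjusted p = 0.0471) without any of kidneys 1 to 10 (0.0538 to 0.454). Over all alternatives these adjusted p ran, in the order given, from 0.0031 to 0.0613, 0.00092 to 0.0521, 0.0115 to 0.194, 4.36e-06 to 0.078, 0.00302 to 0.404 and 0.00369 to 0.454. With only the 6 compared libraries the dendritic cell, endothelial, complement component and coagulation calls were also lost (0.0613, 0.0521, 0.194 and 0.0521), and with library totals the complement component call (0.0805). With an estimated correlation the adjusted p was 0.664 for the dendritic cell, endothelial and coagulation lists and 0.763 for the complement component, heat shock and monocyte lists. Cfb, complement factor B of the alternative pathway, and C8a, of the membrane attack complex, rose by 1.45 ± 0.14 and 3.88 ± 0.418, whereas Eng, an endothelial receptor for TGF-beta, fell by 0.88 ± 0.129 and the co-chaperone gene Bag3 by 0.97 ± 0.141. Among complement receptors and regulators, a list that did not pass the test (3 of 11 rose and 4 fell, adjusted p = 0.201; 0.0332 without kidney 11; range over all alternatives 0.0178 to 0.635), Itgam, a subunit of complement receptor CR3, fell by 3.14 ± 0.523 and Cd59a, which blocks the membrane attack complex, rose by 0.76 ± 0.152.

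In this comparison 8334 genes were called (edgeR, BH-adjusted), 4137 higher and 4197 lower, of which 1951 and 1330 by more than 2-fold, and in 8817 (67.2%) the groups did not overlap, against 10% by chance. With library totals the calls were 3107 higher and 5554 lower, 35.87% higher in place of 49.64%, and the median of all genes went from −0.02 to −0.233. Without kidneys 9 and 11 there were 4248 higher and 4104 lower calls. Kidneys 7 to 9 lay at −0.10, 0.26 and 1.78 in the level of the tubule injury list, so that kidney 9 stood apart in these genes, and ribosomal protein genes stood 0.515, 0.66 and 0.522 above sham.

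Mice given anti-C5 were compared with the isotype group to ask the same of blocking C5. Under anti-C5, tubule injury genes were again lower and tubule segment genes higher than in the isotype group, with kidney 11 between the groups. All 30 proximal tubule genes rose, with a median log2 change of 2.35 (fry BH-adjusted p = 9.57e-05), and 19 of 23 tubule injury genes fell, 21 adjusted over the list alone, with a median of −2.37 (adjusted p = 0.00397). With an estimated correlation the adjusted p was 0.696 for both lists. Slc22a8 was at 377 ± 76.0 CPM (SD, n = 3) and Aqp1 at 1116 ± 376, rises of 1.86 ± 0.144 (SE) and 3.04 ± 0.241 (edgeR BH-adjusted p = 5.94e-06 and 7e-06).

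Krt20 fell by 4.98 ± 1.37 to 33.8 ± 56.3 CPM, Lcn2 by 4.41 ± 1.31 to 104 ± 153 and Flnc by 3.71 ± 1.05 to 13.5 ± 22.6 (edgeR BH-adjusted p = 0.00911, 0.0136 and 0.0106). Without kidney 11 these changes were −9.64, −7.15 and −8.62. The Flnc call was lost with only the 6 compared libraries (adjusted p = 0.0539; range over all alternatives 5.48e-08 to 0.0539). Havcr1 did not pass, at 518 ± 856 CPM and a log2 change of −2.92 ± 1.55 (edgeR BH-adjusted p = 0.123), while without kidney 11 it passed, at −7.41 (adjusted p = 0.000823; range over all alternatives 3.1e-05 to 0.235). With all 12 libraries limma-voom also called Havcr1, at −5.403 (limma-voom BH-adjusted p = 0.0263). Cryab and Anxa1 fell by 1.68 ± 0.159 and 1.75 ± 0.233. The scaffold protein gene Akap12, Cyp27b1, the enzyme that activates vitamin D, and the transcription factor gene Zbtb16 were among the 5 largest falls, at −4.84 ± 0.582, −4.58 ± 0.862 and −4.42 ± 0.68 (edgeR BH-adjusted p = 5.1e-05, 0.000846 and 0.000233). Within the isotype group all of these were lowest in kidney 4. In kidneys 4 to 6 Akap12 stood at 206.8, 878.7 and 997.5 CPM, Cyp27b1 at 9.333, 65.85 and 49.37, and Zbtb16 at 12.83, 55.1 and 66.83. A4gnt stood at 21.9 ± 9.59 CPM and Prok1 at 3.94 ± 1.31, Nat8f6 rose by 6.57 ± 0.557, Nccrp1 by 5.89 ± 0.583 and Pvalb by 5.38 ± 0.609.

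Loop and distal tubule genes rose under anti-C5, 11 of 13 (median 1.87, fry BH-adjusted p = 0.000158), as did 8 of 13 collecting duct genes (median 0.56, adjusted p = 0.00267) and 16 of 21 fatty acid oxidation genes, while 1 of these fell (median 0.80, adjusted p = 0.00397). Slc12a1 rose by 3.50 ± 0.268, Avpr2 by 2.00 ± 0.258 and Decr1 by 1.46 ± 0.162. Of 16 fibroblast and matrix genes 14 fell, and 16 did so adjusted over the list alone (median −1.49, adjusted p = 0.00421), with Acta2, the actin of smooth muscle and myofibroblasts, at −2.34 ± 0.321. Of 13 cell death genes 9 fell (median −0.76, adjusted p = 0.00397), with the death receptor gene Tnfrsf10b at −1.80 ± 0.282. Of 11 antioxidant genes 7 fell and 2 rose (median −1.29, adjusted p = 0.00397), and Gstm1 was one that rose, by 1.27 ± 0.126. Of 7 endothelial activation genes 4 fell and 1 rose (median −1.11, adjusted p = 0.00397), with Thbd at −1.70 ± 0.174. For each of these 7 lists the adjusted p with an estimated correlation was 0.696, and the other counts were the same adjusted over the list alone.

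Neutrophil genes did not pass as a list under anti-C5: 3 of 13 fell and G0s2 rose, 2 and 1 adjusted over the list alone, with a median of −0.86 (fry BH-adjusted p = 0.0887; with an estimated correlation adjusted p = 0.76). The levels of this list in kidneys 10 to 12 were −0.04, 3.07 and 0.35 on the log2 scale above the sham mean, against 2.88 ± 0.528 in the isotype group (SD, n = 3). Without kidney 11 the list passed (adjusted p = 9.8e-05; range over all alternatives 9.8e-05 to 0.267). S100a8 stood at 13.0 ± 17.8 CPM with a change of −0.50 ± 0.795 (edgeR BH-adjusted p = 0.603), and without kidney 11 it fell by 2.76 (adjusted p = 0.00114; range over all alternatives 0.00114 to 0.983). Retnlg fell by 2.50 ± 0.597, and by 1.60 without kidney 6 (adjusted p = 0.0188; range over all alternatives 0.000282 to 0.0211).

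Another 3 lists were called under anti-C5 but lost the call without single kidneys. Dendritic cell genes (6 of 7 rose and 1 fell, median 1.34, fry BH-adjusted p = 0.0147) lost it without kidney 5, 6 or 12 (0.0521, 0.0533 and 0.0586) and with only the 6 compared libraries (0.0561). Endothelial genes (6 of 12 fell, median −0.42, adjusted p = 0.0321) lost it without kidney 5, 6, 10, 11 or 12 (0.103, 0.112, 0.0751, 0.0584 and 0.0769) and with the 6 libraries (0.0561). Coagulation genes (1 of 11 rose and 7 fell, median −2.07, adjusted p = 0.048) lost it without any of kidneys 1 to 6, 8, 10 and 12 (0.0587 to 0.247), with the 6 libraries (0.0537) and with upper-quartile factors (0.051). Over all alternatives the adjusted p of these lists ran from 0.00417 to 0.0586, 0.00222 to 0.112 and 8.5e-06 to 0.247. Camera gave adjusted p = 0.733 with an estimated correlation for the dendritic cell and coagulation lists and 0.758 for the endothelial list. H2-Eb1 rose by 1.35 ± 0.283 and F5 by 1.87 ± 0.137, and Eng fell by 0.81 ± 0.129. Genes of complement components did not pass as a list under anti-C5 (4 of 16 rose and 2 fell, 4 and 1 adjusted over the list alone, median 0.10, adjusted p = 0.0748), with adjusted p = 0.043 without kidney 4 and 0.0395 without kidney 9 in a range of 0.0182 to 0.185 over all alternatives. C8a rose by 3.78 ± 0.418 and Cfb by 1.24 ± 0.139. Nor did complement receptors and regulators (2 of 11 rose and 2 fell, median −0.28, adjusted p = 0.347), with adjusted p = 0.038 without kidney 11 in a range of 0.0247 to 0.785, though Cd59a rose by 0.75 ± 0.152 and Itgam fell by 2.11 ± 0.487, or 3.20 without kidney 11.

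Calls under anti-C5 against isotype numbered 7919 (edgeR, BH-adjusted), 4006 higher and 3913 lower, of which 1821 and 1082 by more than 2-fold. The groups did not overlap in 8230 genes (62.7%), against 10% by chance. With library totals 3106 were higher and 5111 lower, 37.8% higher in place of 50.59%, and the median of all genes went from −0.01 to −0.194. Without kidneys 9 and 11 there were 4144 higher and 4009 lower calls. Ribosomal protein genes stood 0.262, 0.642 and 0.728 above sham in kidneys 10 to 12, and red cell genes, which were not called as a list (median 1.53, fry BH-adjusted p = 0.504), stood 2.59 above sham in kidney 11.

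**Figure D2:**
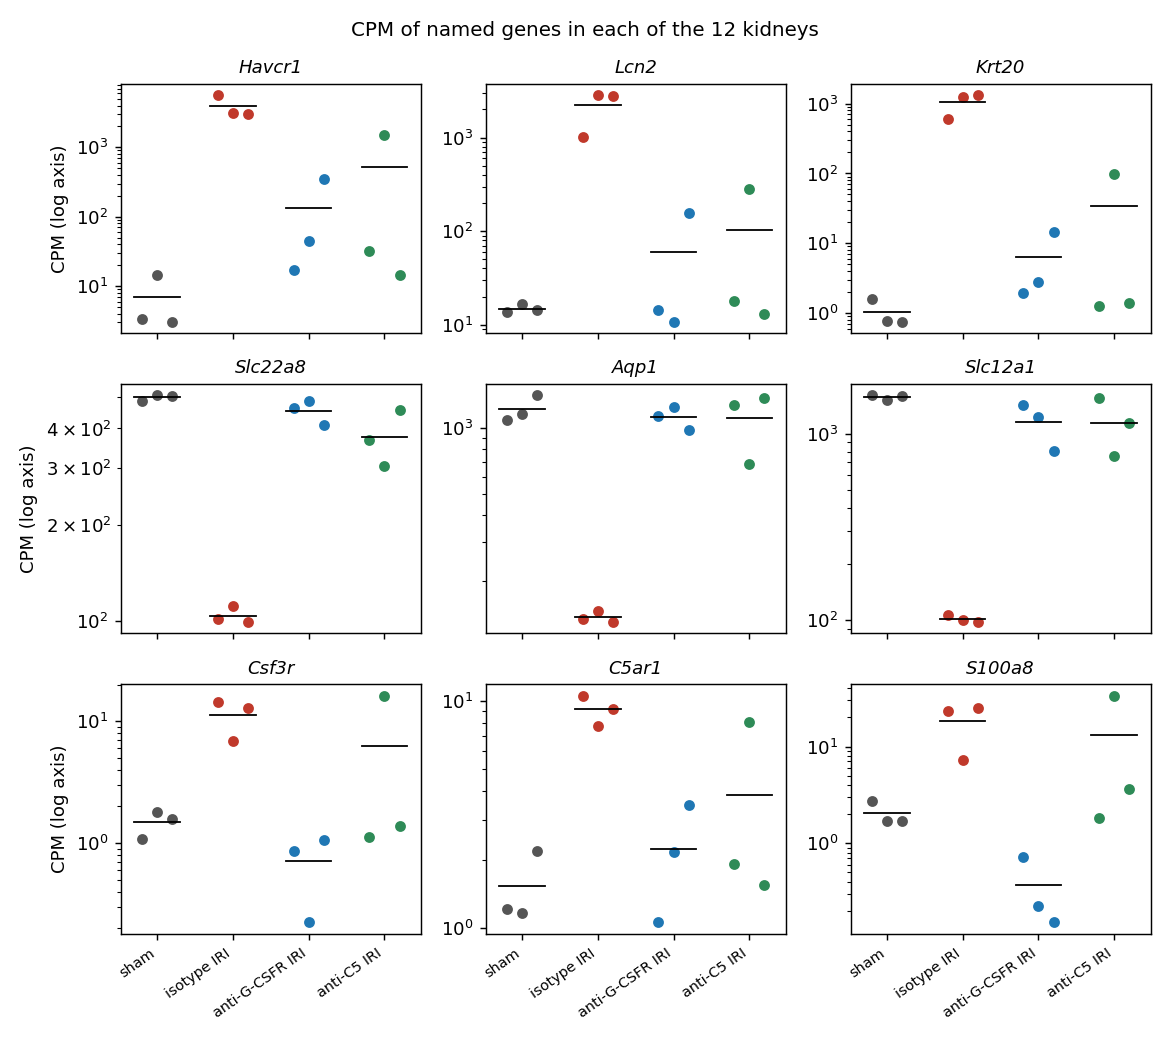
CPM of 9 genes in each of the 12 kidneys by group, on a log axis, with points for kidneys and a line for the group mean. Slc22a8, Aqp1 and Slc12a1 are lowest in all 3 isotype kidneys, and kidney 11 lies above kidneys 10 and 12 in Havcr1, Lcn2, Krt20, Csf3r, C5ar1 and S100a8.

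The 2 antibodies were then set against each other and against sham surgery. Between anti-G-CSFR and anti-C5 kidneys no gene was called by edgeR after BH adjustment (0 of 13124; 207 at an unadjusted p below 0.05, with 656.2 given by chance; 0 by limma-voom with or without sample weights). DESeq2 called 2, Cxcr2, the neutrophil chemokine receptor gene, and S100a8, both lower under anti-G-CSFR, and Cxcr2 is named here because its value was seen. Cxcr2 stood at 0.0689 ± 0.0662 CPM (SD, n = 3) under anti-G-CSFR and 3.30 ± 4.49 under anti-C5, and S100a8 at 0.367 ± 0.313 and 13.0 ± 17.8 CPM, with a log2 change of −5.07. No list was called by fry (0 of 25; neutrophil genes median −3.47, adjusted p = 0.502, with an estimated correlation adjusted p = 0.201), though 11 of the 13 neutrophil genes were lower and 3 of 4 fat and adrenal genes higher (median 3.69, adjusted p = 0.732) adjusted over the list alone. Neutrophil list levels were −0.79, −1.10 and −0.90 in kidneys 7 to 9 and −0.04, 3.07 and 0.35 in kidneys 10 to 12, so kidney 11 stood far above the others. Camera called 12 lists with its preset correlation and 0 with an estimated one. The groups did not overlap in 562 genes (4.28%, with 10% by chance), and without kidneys 9 and 11 edgeR again called 0 genes (104 at an unadjusted p below 0.05). With single kidneys left out the count at an unadjusted p below 0.05 moved by over 1.5 times without kidney 10 (523) and kidney 12 (585), and 0 genes were called in each.

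Against sham, edgeR also called 0 genes after BH adjustment in either antibody group. For anti-G-CSFR the count at an unadjusted p below 0.05 was 778, DESeq2 called 1, the protease inhibitor gene Spink8, limma-voom 0, limma-voom with sample weights 305 and edgeR on only the 6 compared libraries 43. Spink8, named after its value was seen, stood at 11.3 ± 1.79 CPM in sham kidneys and 20.9 ± 2.85 under anti-G-CSFR (SD, n = 3). For anti-C5 the count at an unadjusted p below 0.05 was 1487, DESeq2 called 112 (70 higher and 42 lower, with 11707 genes left without an adjusted p), and limma-voom with or without weights and edgeR on the 6 libraries 0. Groups did not overlap in 2411 genes (18.4%) and 2356 (18%), against 10% by chance. No list was called by fry in either comparison (0 of 25). For tubule injury genes the median log2 change was 0.46 under anti-G-CSFR (adjusted p = 0.96) and 1.64 under anti-C5 (0.564), and for proximal tubule genes −0.13 and −0.19. Neutrophil genes had medians of −1.36, or −1.05 with Clec4e at its bound (0.857), and 2.35 (0.564), and in the second 9 of 13 were higher adjusted over the list alone. Adjusted in the same way, 1 of 9 podocyte genes was lower in the first, and in the second 2 of 9 podocyte genes were lower and 1 each of the monocyte, urothelial and granule precursor genes higher. Kidney 11 carried the tubule injury and neutrophil values under anti-C5. Levels in kidneys 10 to 12 were 0.23, 2.96 and 0.08 for tubule injury genes and −0.04, 3.07 and 0.35 for neutrophil genes. Without kidneys 9 and 11 the counts called were again 0, with 1309 and 1254 at an unadjusted p below 0.05. With kidney 1 alone left out, the counts at an unadjusted p below 0.05 were 288 for anti-G-CSFR and 666 for anti-C5, and with kidney 8 alone left out that for anti-G-CSFR was 366, where chance gives 656.2.

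How far each kidney lay from sham was measured over the 500 genes most clearly higher in the isotype group, on a scale from the sham mean (0%) to the isotype mean (100%). Kidneys 7 to 9 lay at 0.833%, 1.46% and 17.8%, and kidneys 10 to 12 at 4.50%, 41.3% and 3.01%, means of 6.70 ± 9.61% under anti-G-CSFR and 16.3 ± 21.7% under anti-C5 (SD, n = 3). Over the 500 genes most clearly lower they lay at 2.14%, 3.58% and 11.6% and at 2.93%, 26.1% and 2.89%, so that kidneys 9 and 11 carried the group means over both sets. Against isotype, the first 500 genes had a median log2 change of −1.53 under anti-G-CSFR and −1.35 under anti-C5, and the second 500 of 1.96 and 1.86. These genes were chosen on the same isotype kidneys and are not independent evidence of their direction. They were also ranked with a spread estimated over all 12 libraries, antibody kidneys included. Genes in which kidney 9 or 11 stood apart from its group could rank lower for that reason, which would place both kidneys nearer sham. The higher genes were then chosen in other sham and isotype kidneys than those they were measured against, in fits without antibody kidneys. Over these, kidneys 7 to 9 lay at −4.41%, −0.187% and 28.1% and kidneys 10 to 12 at 1.63%, 56.3% and −2.58%. Over the lower genes of that choice they lay at −1.55%, 1.22% and 13.7% and at 0.932%, 28.3% and −1.70%. Kidneys 9 and 11 lay at 41.35% and 68.6% over the fixed tubule injury list and at 13.4% and 25.7% over the fixed proximal tubule list, which fell in isotype kidneys. The choice planned in their place was of genes called in the other antibody group against sham, in a fit on only those 6 libraries, and gave 0 genes from anti-C5 and at most 1 from anti-G-CSFR. Without its minimum fold that 6-library fit gave 41 higher and 2 lower genes from anti-G-CSFR against sham, where the main fit called 0. The 41 had a median log2 change of −0.02 in anti-C5 against isotype, with no shift detected (fry p = 0.928, with an estimated correlation p = 0.998).

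Calls were then compared between contrasts. Of the genes called in the isotype group against sham, 7375 were also called under anti-G-CSFR against isotype, all with the opposite sign, 3698 up then down (1345.4 by chance for independent lists) and 3677 down then up (1271.6). For anti-C5 the count was 7014, of which 7013 had the opposite sign, 3448 up then down (1254.3 by chance) and 3565 down then up (1231.3). Both antibodies shared 7510 calls against isotype, all of the same sign, 3820 higher (1262.8 by chance) and 3690 lower (1251.4). Across genes, which are not independent replicates, the log2 changes of the 2 antibodies against isotype had r = 0.964. In 30 simulations without any antibody effect, with the isotype and antibody groups drawn around the same means, at most 1 gene was shared with the opposite sign in either pair. A mean of only 0.0667 and 0.167 genes was called there under anti-G-CSFR and anti-C5 against isotype, so hardly any could be shared. That count therefore does not show how many opposite-sign calls the shared isotype libraries add when as many genes are called as in the data. Mean r of the log2 CPM changes in isotype against sham with those under anti-G-CSFR and anti-C5 was −0.101 and −0.102 in these simulations and −0.979 and −0.968 in the data, with covariances of −0.0288 and −0.0291 against −1.242 and −1.143. On log2 CPM the r between the antibodies was 0.982 and the covariance 1.118. In 100 simulations of unchanged groups, with the isotype libraries drawn too, all around the isotype means, mean r was 0.492 and mean covariance 0.0305. The differences in covariance were −1.214 and −1.114 for these pairs and 1.088 between the antibodies. These comparisons use the same 3 isotype libraries, which cannot be split with 2 or more in each part. The simulations include that sharing but draw genes independently of each other, so part of the excess may still come from the shared controls.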

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

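The fits without kidneys 9 and 11, the library orders in fry and the injury position were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because no kidney number occurs in 2 groups. No alternative reversed a called list or a called named gene; reversals among the other genes were not counted. The filters without a minimum and at 1 CPM in 3 libraries removed no gene and test nothing. For isotype against sham, anti-G-CSFR against isotype and anti-C5 against isotype, the genes called numbered 8266, 8379 and 7978 with DESeq2, 8285, 8363 and 7992 with limma-voom, and 8205, 8329 and 7914 with RLE factors. With library totals 88.61%, 87.64% and 88.62% of the calls kept their direction. With 1 library left out the counts ran from 7208 to 8562, 7218 to 8712 and 6644 to 8336, and stayed at 0 in the other 3 comparisons. The highest count of each range came without kidney 4, of the isotype group that these comparisons share. Kidney 4 differed from kidneys 5 and 6 by a chi-square per degree of freedom of 46.1 and 48.4, while kidneys 5 and 6 differed by 5.46. A test against a 1.5-fold change gave 3585, 3555 and 3061, fewer by its construction. DESeq2 called 2 genes in anti-G-CSFR against anti-C5, 1 in anti-G-CSFR against sham and 112 in anti-C5 against sham. In anti-G-CSFR against sham the fit on 6 libraries called 43 and limma-voom with sample weights 305; for these gains the cause was not tested.

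Of the gene lists, camera with an estimated correlation called 0 in all 6 comparisons, against 15, 16 and 12 by fry in the first 3. Camera with its preset correlation called 10, 9 and 8 in these and 12, 8 and 12 in anti-G-CSFR against anti-C5, anti-G-CSFR against sham and anti-C5 against sham, where fry called 0; camera compares a list with other genes, which fry does not. Without kidneys 9 and 11 the lists called numbered 19, 20 and 19. With 1 library left out they ran from 11 to 17, 10 to 19 and 9 to 15, lowest in the second without kidney 5 and highest without kidney 11; the cause was not tested. Over 100 orders of the libraries fry called 15 to 16, 14 to 16 and 11 to 12. The complement component list was called in 43 of these orders in isotype against sham and 99 in anti-G-CSFR against isotype, where the monocyte list was called in 61 and the heat shock list in 93, and the coagulation list in 83 in anti-C5 against isotype. Over single lists and alternatives, 132 values lost a call, 78 gained one and 2640 did neither; over named genes these numbers were 22, 15 and 5187. The correlation of both antibodies' changes stayed between 0.942 and 0.975 with 1 library left out. At this depth a single count was worth 0.0555 to 0.0773 CPM, so levels near that value, such as those of Clec4e, Clec4d and Cxcr2 under anti-G-CSFR, are bounded by counting and not measured closely.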

Other observations

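The tests of scaling, of uninjured kidneys, of less injury and of less blood were chosen after the results were seen, and the fat test and the splits before. Several cell types and pathways were measured without a list call. In the isotype group against sham these were red cell genes (0 of 4 passed, median log2 change −0.42, fry BH-adjusted p = 0.72), podocyte genes (2 of 9 rose and 3 fell, median 0.02, mean −0.04 and test direction down, 0.821), fat and adrenal genes (1 of 4 rose, median 0.04, 0.704), interferon response genes (1 of 22 rose and 5 fell, 1 and 4 adjusted over the list alone, median −0.15, 0.437) and cell cycle genes (1 of 17 fell, median 0.18, 0.646). A further 5 lists missed the threshold there but passed without 1 library: endothelial genes (4 of 12 rose and 1 fell, 0.066; 0.00258 without kidney 4), urothelial genes (2 of 7 rose and 1 fell, 0.111; 0.0362 without kidney 9), heat shock genes (3 of 10 rose and 2 fell, 0.276; 0.0402 without kidney 12), complement receptors and regulators (4 of 11 rose and 2 fell, 0.118; 0.0223 without kidney 11) and complement components. Of 16 complement component genes 2 rose and 5 fell, 1 and 4 adjusted over the list alone, with a median of 0.23 but a mean of −0.42 and a test direction down (0.0523; 0.0322, 0.0164 and 0.0245 without kidney 7, 9 or 11). In that list C8a and Cfb fell by 4.47 ± 0.418 and 1.27 ± 0.139. Over all alternatives the adjusted p of these 5 lists ran from 0.00258 to 0.253, 0.0257 to 0.32, 0.0108 to 0.767, 0.0115 to 0.365 and 0.00345 to 0.163. Of the granule precursor list Chil3 alone was measured, and it rose by 5.42, while of the B and plasma cell list Jchain alone was, and it fell by 1.18; no T or NK cell gene was in the table.

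Under anti-G-CSFR against isotype the lists without a call were red cell (0 of 4 passed, median −0.09 and test direction up, fry BH-adjusted p = 0.977), podocyte (4 of 9 fell, 3 adjusted over the list alone, 0.175; 0.024 without kidney 9), urothelial (3 of 7 rose and 2 fell, median 0.52 and test direction down, 0.977), fat and adrenal (1 of 4 fell, median 0.87 and test direction down, 0.755), chemokine (5 of 12 fell, 0.0979; 0.018 without kidney 11), interferon (6 of 22 rose and 1 fell, 4 and 1 adjusted over the list alone, 0.238), cell cycle (1 of 17 rose and 2 fell, 1 and 0 adjusted over the list alone, 0.491) and hypoxia genes (8 of 17 rose and 4 fell, 0.119; 0.0281, 0.0423, 0.0455 and 0.0324 without kidney 9, 10, 11 or 12). Under anti-C5 they were monocyte (2 of 16 rose and 5 fell, 1 and 4 adjusted over the list alone, 0.313; 0.0156 without kidney 11), podocyte (4 of 9 fell, 0.126; 0.0489 without kidney 9), urothelial (1 of 7 rose and 2 fell, 0.313), fat and adrenal (1 of 4 fell, 0.0793; 0.0225 and 0.0481 without kidney 7 or 9), chemokine (1 of 12 fell, 0.224; 0.0133 without kidney 11), interferon (6 of 22 rose and 1 fell, 5 and 1 adjusted over the list alone, 0.168), cell cycle (1 of 17 rose, 0.51), hypoxia (8 of 17 rose and 4 fell, 0.209) and heat shock genes (2 of 10 rose and 3 fell, 0.355). Over all alternatives the adjusted p ran for podocyte, chemokine and hypoxia genes under anti-G-CSFR from 0.019 to 0.393, 0.00131 to 0.411 and 0.00737 to 0.722. For monocyte, podocyte, fat and adrenal, and chemokine genes under anti-C5 it ran from 0.00785 to 0.894, 0.0323 to 0.318, 0.0225 to 0.237 and 0.00197 to 0.678.

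Most antibody-treated kidneys lay near sham in injury genes, with kidneys 9 and 11 between sham and isotype. A scaling difference between libraries as the whole source is argued against, since at least 87.64% of the calls of each antibody against isotype kept their direction with library totals. Over the tubule injury list kidneys 9 and 11 lay at 41.35% and 68.6% of the way from sham to isotype, above the bound of 16 set by the highest sham kidney plus 2 SD. Over the proximal tubule list they lay at 13.4% and 25.7% beside a highest sham value of 2.71%. These 2 kidneys were picked because they stood apart, and the bound was set afterwards, so the values describe raised injury genes and are not a test. For kidneys 7, 8, 10 and 12, at −2.28%, 5.96%, 5.28% and 1.81% beside a highest sham value of 5.557%, a kidney that was never injured and a kidney protected by the antibody cannot be told apart, because no measure of the ischaemia itself was analysed here and the labels do not say that the kidney taken was the operated one. A hypothesis left open is that either antibody may lessen injury, to a degree that differs between animals.

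Neutrophil genes were lowest under anti-G-CSFR, at list levels of −0.7871, −1.098 and −0.898 on the log2 scale below the sham mean. Uninjured sham kidneys lay at −0.107 or above, and the bound of 2 SD below them was −0.305, which all 3 anti-G-CSFR kidneys lay below. That bound was set after the levels were seen, on 3 sham kidneys of mice given no antibody. It therefore does not decide whether less injury alone was the whole source. The test of this list against sham missed the threshold (fry BH-adjusted p = 0.857), and the exact permutation p of the levels was 0.1, the smallest that 3 against 3 allows. Less blood left in the vessels stays open: red cell genes differed from sham by −0.445 and neutrophil genes by −0.928, a gap of 0.483 with an SE of 0.829. A hypothesis is that blocking G-CSFR may lower the neutrophils of the kidney below their resting number, which was not tested on cells.

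Fat cell genes differed between kidneys of one group: Adipoq, which encodes adiponectin, stood at 0.198, 7.01 and 14.1 CPM in kidneys 7 to 9, and Cidec, a lipid droplet gene, at 1.26, 9.32 and 22.4 CPM. A candidate source is fat tissue taken with some kidneys, for which 11 other fat cell genes were listed, of which 3 were measured. Over 12 kidneys their level followed that of Adipoq, Plin1 and Cidec, with Spearman's rho = 0.7762 (permutation p = 0.00479) and r = 0.792 (permutation p = 0.00189), or r = 0.661 without the 2 farthest kidneys. This was the only such relation computed. The permutations moved kidneys between the groups, so differences between groups as well as within them enter these p. The rho lay between the bounds set before the results were seen, short of the one for this source, so the test did not decide for or against it. With 3 test genes it does not settle whether the fat was attached tissue or fat cells within the kidney.

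The splits of 6 kidneys into 3 and 3 number 10, too few for a share under 0.05. Every split but the real one mixes kidneys of both groups, so a large real difference enters the spread and lowers the count. Low counts in the other splits therefore do not show what groups without a difference would give. In the fit on the 6 compared libraries the real and the highest other counts of genes were 8111 and 0 for isotype against sham, 7803 and 0 for anti-G-CSFR against isotype, 6429 and 0 for anti-C5 against isotype, 0 and 0 for anti-G-CSFR against anti-C5, 43 and 1 for anti-G-CSFR against sham, and 0 and 0 for anti-C5 against sham. For lists they were 18 and 0, 13 and 0, 9 and 0, 0 and 0, 0 and 0, and 0 and 1. A count as large as the real one came from 1 split, the real one, in the first 3 comparisons and in anti-G-CSFR against sham for genes, and from all 10 elsewhere.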
